A study of Rattus norvegicus with 6 samples.

How the data were processed

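RNA of 6 samples was measured on rat Affymetrix arrays, 3 of the clonal cholangiocarcinoma strain BDEsp-TDECC and 3 of the clonal fibroblastic strain BDEsp-TDESM, called TDECC and TDESM below. Groups and replicate numbers came from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made by the standard Affymetrix procedure. The deposited values are on the log2 scale and were made by the authors with RMA, per the submitters' processing notes, and the RMA version is not given in the sources used here. RMA as usually run corrects background, brings all arrays to the same distribution and summarises probes per probe set; the 6 arrays here had nearly equal quantiles. Such scaling removes any difference between strains in total mRNA. The deposited table carries no detection calls, so no probe set could be called absent. The labels describe growth as a 3-dimensional co-culture in collagen gel and name TGF-beta inhibitors for all 6 samples alike, so neither factor was analysed. Other samples of the series are not analysed here.

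From the deposited values the following was computed in R 4.3.3 with limma 3.58.1. Of 31099 probe sets, 57 were controls and 21268 were listed in the platform annotation; 20826 named 1 gene symbol, 436 named several and 9831 were not listed and stayed unnamed. Entrez identifiers of 99.7% of the named probe sets were found in the RefSeq table of assembly GRCr8, and 0 symbols changed. A gene was represented by its probe set with the highest mean over the 6 arrays (4525 genes had more than 1), which left 14217 genes with no filter on dim ones. Other probe sets of a gene can read it differently, so differences of named genes that moved by more than 1.5 times with the mean of all probe sets are given both ways. Each gene was tested with limma (lmFit and eBayes), TDESM minus TDECC, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. No replicate block was used.

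Before the data were examined, 27 gene lists were written, of which 26 were tested and 1, of housekeeping genes, served for scaling; 596 of 673 list symbols were measured, 10 through an older symbol, and 21 genes stood in more than 1 tested list. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Fry tests whether members move on balance in 1 direction and does not compare a list with other genes. The named genes were fixed by a rule written at the same time: 14 genes chosen for the tumour type, of which 1, Tgfbr2, is not analysed here; the 6 largest differences each way among genes past the threshold with non-overlapping groups; and from each list up to 2 members each way past the threshold, of which up to 3 are printed. A best known member that failed the threshold could be added; those added were picked after their values were seen, from a longer set, and say nothing of the stability of members not named.

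Alternatives listed before the data were examined were cyclic loess, centring on housekeeping or on ribosomal protein genes, leaving out the dimmest 33.3% of genes, the mean of all probe sets, eBayes with trend and robust settings, the replicate number as a block, each array left out in turn, a minimum log2 difference of 1, and probe sets in place of genes. Centring each array on the poly-A control transcripts (dap, lys, phe and thr) was added after seeing the data. The limma and camera steps were tested on simulated data for TDESM against TDECC with 14217 genes, 200 of them changed. Limma recovered 54% of genes changed by a log2 of 1 and 88% of those changed by a log2 of 2, all with the right sign. Of its calls 7.19% were unchanged genes, above the nominal 5%, though in a single simulated draw. Camera called a list of 20 raised genes and did not call a list of 20 unchanged ones. The simulated genes varied independently, so this does not test the preset correlation. Each had the same spread in both groups, though TDECC arrays varied more than TDESM arrays.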

Results

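Gene expression was measured on 6 rat expression arrays, 3 from each of 2 clonal cell strains. Both strains came from tumours that arose after spontaneously transformed rat cholangiocytes, the cells that line bile ducts, had been placed into the bile duct of rats. BDEsp-TDECC, here TDECC, is a cholangiocarcinoma (bile duct cancer) cell strain, and BDEsp-TDESM, here TDESM, is a fibroblastic strain described in the labels by high expression of Acta2, the smooth muscle actin of myofibroblasts. Each array gave log2 values for 31099 probe sets, with medians between 5.80 and 5.86, and the number of arrays limits the precision. Arrays of one strain correlated at 0.974 to 0.977 across genes in TDECC and at 0.994 to 0.997 in TDESM, while arrays of different strains correlated at 0.824 to 0.853. No pair of arrays shared more than 5.74% of identical probe set values, so each was counted as a separate sample. Each group is a single clonal strain and nothing says that its arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The labels give all arrays the same culture and TGF-beta inhibitor text and do not say which cultures were treated, so no treatment was compared.

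The comparison asked how the fibroblastic strain differs from the cancer cell strain. TDESM carried high levels of matrix genes that were mostly near the array background in TDECC, and TDECC carried high levels of keratins and junction genes that were mostly near background in TDESM. Of 20 contractile genes 16 were higher in TDESM, some of them from well above background in TDECC, such as Cnn2 at 10.51. With an estimated correlation camera called none of these lists (adjusted p = 0.0600 for matrix and for contractile genes, and 0.0664 for keratin and junction genes). Col1a2, a chain of type I collagen, stood at 14.41 ± 0.05 (SD, n = 3) in TDESM and 3.69 ± 0.51 in TDECC. Krt19, a keratin of bile duct epithelium, stood at 3.58 ± 0.17 in TDESM and 14.33 ± 0.19 in TDECC. Of 14217 genes tested with limma, 6065 (42.7%) passed an adjusted p of 0.05, of which 3135 were higher and 2930 lower in TDESM. Of these, 1906 were at least 2-fold higher and 1717 at least 2-fold lower, and 209 were at least 32-fold higher and 140 at least 32-fold lower. The values of both strains did not overlap for 7625 genes (53.6%), against 10% given by chance for 3 against 3. The split by direction rests on arrays scaled to equal distributions: centred on the added poly-A control transcripts instead, a choice made after seeing the data, 12187 genes passed, 905 higher and 11282 lower, and the median gene moved by -1.27. Changes below are therefore relative to the median gene of the deposited values, and log2 differences against a strain at background are likely smaller than the true ones. Under the poly-A centring, adjusted p followed the size of the difference, whatever the spread of the gene. Calls of genes and lists gained or lost there therefore do not weigh that spread.

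**Figure D1:**
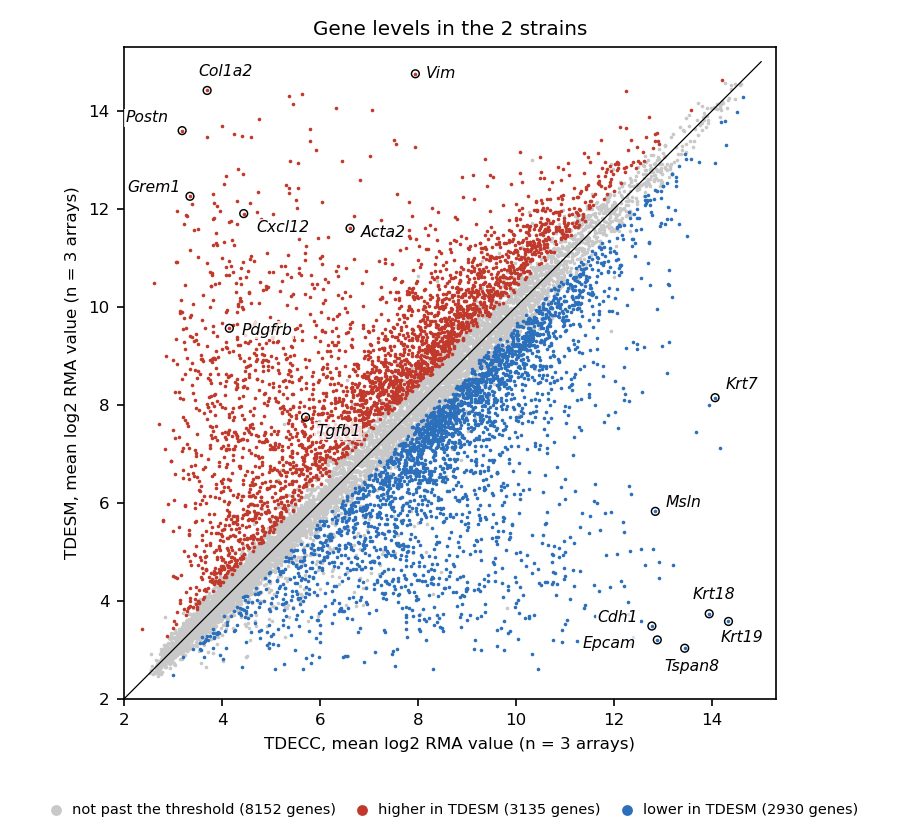
Mean log2 RMA value of each of 14217 genes in TDECC (horizontal axis) and TDESM (vertical axis), 3 arrays each, with the line of equal values; red points are the 3135 genes higher and blue points the 2930 genes lower in TDESM at a limma adjusted p under 0.05. Col1a2 and Postn lie near the upper left corner and Krt19, Krt18 and Tspan8 near the lower right; centred on the poly-A control transcripts, 905 genes were higher and 11282 lower.

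Acta2 was higher in TDESM, at 11.60 ± 0.07 against 6.61 ± 0.95 (SD, n = 3 each), a log2 difference of 4.99 (SE 0.43, limma adjusted p = 1.10e-04). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. The strain is described by this gene, so the value checks the labels and is no independent finding.

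The largest rises in TDESM were those of Col1a2 (log2 difference 10.72, SE 0.25), Postn (10.41, SE 0.18), Prss23 (9.77), Nid1 (9.67, or 4.91 with the mean of its probe sets), Fn1 (9.67) and Serpinh1 (9.27, or 5.12 with that mean). Postn encodes periostin, Nid1 the basement membrane protein nidogen, Fn1 fibronectin, and Serpinh1 the collagen chaperone HSP47, the last read by a probe set shared with other transcripts. The largest falls were those of Krt19 (-10.76, SE 0.15), Tspan8 (-10.41, SE 0.28), Krt18 (-10.21), Epcam (-9.68), Cdh1 (-9.29, or -4.79 with the mean of its probe sets) and Gabrp (-9.23). Epcam and Cdh1 encode epithelial adhesion proteins, the latter E-cadherin. Each of these 12 genes had non-overlapping groups, with limma adjusted p between 9.79e-08 and 4.01e-07.

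Of 32 measured genes of the fibrillar matrix, 28 rose in TDESM and 0 fell, as did 16 and 0 of 20 contractile genes. Matrix members included Col1a1 (log2 difference 9.08), Lox, a collagen cross-linking enzyme (8.29), Col1a2 and Postn. Contractile members included Tpm2, a tropomyosin (8.94, or 5.6 with the mean of its probe sets), and Tagln, transgelin (8.71). Dcn, decorin, stood at 3.67 in TDESM and 3.87 in TDECC, and Myh11, smooth muscle myosin heavy chain, at 6.87 and 7.20, neither past the threshold; both were picked after their values were seen. Camera gave adjusted p = 1.27e-17 for the matrix list and 3.88e-07 for the contractile list, and adjusted p = 0.0600 for each with an estimated correlation. The counts adjusted over the list alone were the same.

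Among 23 fibroblast markers, 14 rose and 1 fell in TDESM, relative to the median gene; centred on the poly-A controls their median was -0.19. Vim, vimentin, rose by 6.81, Cdh11, a mesenchymal cadherin, by 8.61, Thy1 by 7.57 and Pdgfrb, a platelet-derived growth factor receptor read by a shared probe set, by 5.41, all on the log2 scale. With the mean of all probe sets Cdh11 rose by 4.10 and Pdgfrb by 3.17. Hoxa5 fell by 1.60. Fap, fibroblast activation protein, stood at 4.28 ± 0.13 in TDESM and 4.18 ± 0.28 in TDECC, both near background. S100a4 was high in both, at 14.15 ± 0.08 and 13.72 ± 0.36 (SD, n = 3). The highest value of an array was 14.60 to 14.76, so a difference of S100a4 may be compressed. Neither gene passed the threshold, and both were picked after their values were seen. Camera gave adjusted p = 5.34e-06, and adjusted p = 0.0600 with an estimated correlation. Of 17 stellate cell and pericyte markers 9 rose and 0 fell, among them Abcc9 (3.93, or 2.16 with the mean of its probe sets) and Pdgfrb (camera adjusted p = 0.0153; adjusted p = 0.175 with an estimated correlation; 1 lower when adjusted over the list alone), with a median of -0.76 centred on the poly-A controls. That call was lost without TDECC replicate 1 (adjusted p = 0.0522).

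Among 34 keratin and epithelial junction genes, 31 were lower in TDESM and 0 higher, led by Krt19 and Krt18. Krt7, a bile duct keratin, was still at 8.14 ± 0.20 in TDESM against 14.06 ± 0.18 in TDECC (SD, n = 3). Camera gave adjusted p = 4.40e-21, and adjusted p = 0.0664 with an estimated correlation; adjusted over the list alone, 31 were lower and 1 higher. The cholangiocyte list split: 9 of 22 genes were lower in TDESM, including Tspan8 and Cd24 (-8.97), and 2 were higher, Spp1, osteopontin (5.20), and Pkd2, a cilium-associated channel (5.05, or 2.52 with the mean of its probe sets). Camera gave adjusted p = 0.00712, and adjusted p = 0.175 with an estimated correlation, and adjusted over the list alone 10 were lower and 2 higher. Of 21 mucin and carcinoma genes, 10 were lower and 1 higher (camera adjusted p = 0.00430; adjusted p = 0.209 with an estimated correlation; 13 lower and 1 higher adjusted over the list alone). Plau, urokinase, differed by -7.73, Ceacam1 by -7.27 and Msln, mesothelin, by -7.02. Cd44 was higher by 1.15, a call lost without TDESM replicate 2 (adjusted p = 0.0555) or 3 (adjusted p = 0.0560) and a sign that turned, at -0.12, when arrays were centred on the poly-A controls.

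**Figure D2:**
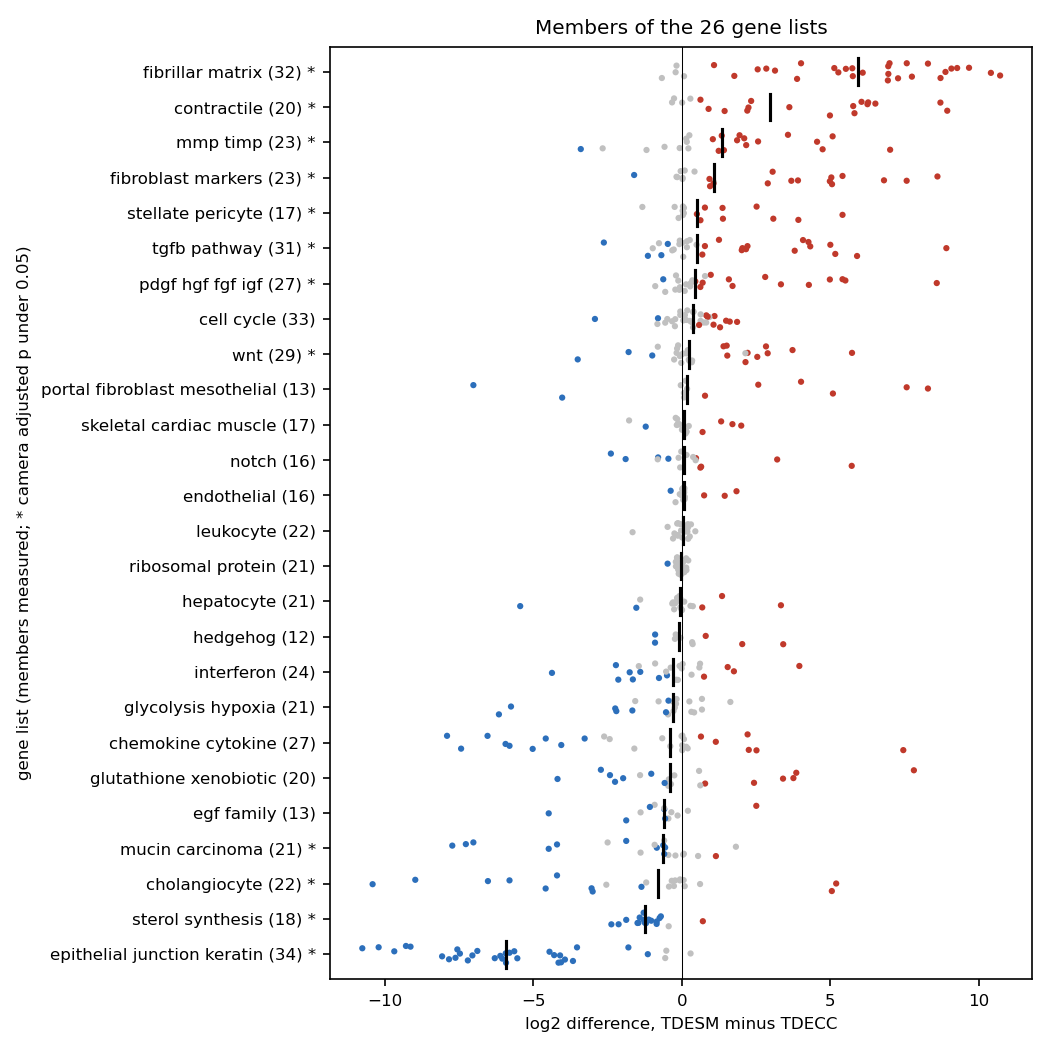
Log2 difference, TDESM minus TDECC (horizontal axis), of each measured member of 26 gene lists (rows, sorted by median), as a point that is red or blue where limma's adjusted p over all genes was under 0.05 and grey otherwise; black bars are list medians, and an asterisk marks a camera adjusted p under 0.05. Fibrillar matrix genes have the highest median, 5.93, and keratin and junction genes the lowest, -5.92, while centring on the poly-A controls moved the median of all genes by -1.27.

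**Figure D3:**
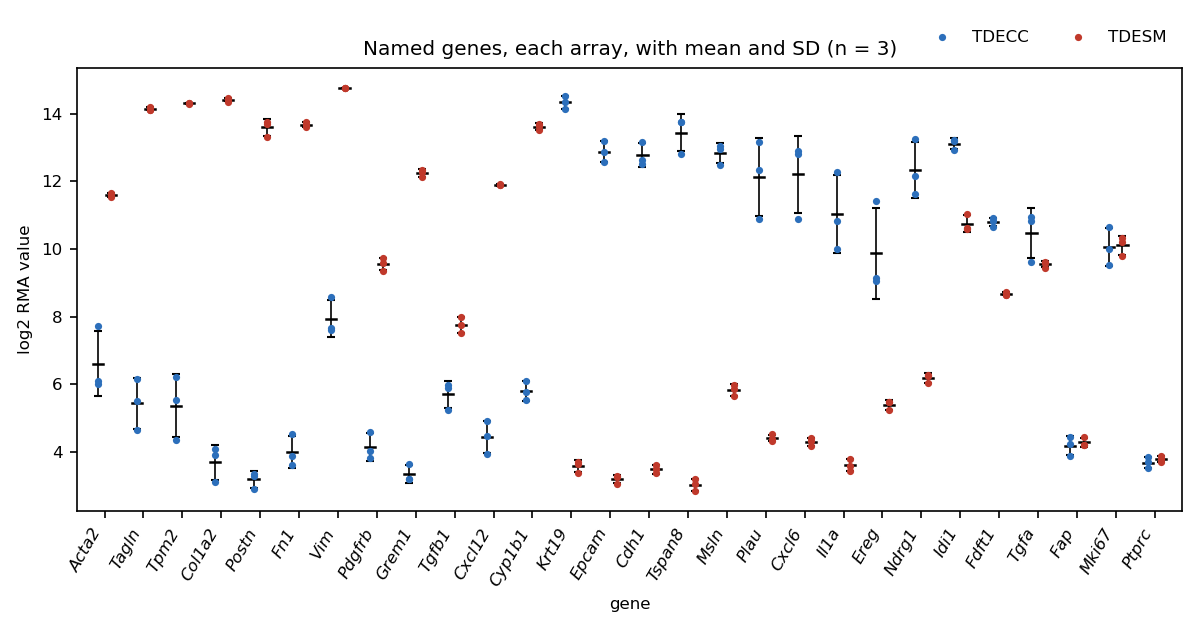
Log2 RMA values (vertical axis) of selected named genes (horizontal axis) on each of the 3 TDECC arrays (blue) and 3 TDESM arrays (red), with the mean and SD in black. Acta2 lay at 6.61 in TDECC and 11.60 in TDESM, and Fap lay near 4 in both.

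Of 31 genes of the TGF-beta pathway, 15 were higher and 4 lower in TDESM, relative to the median gene; their median was -0.77 centred on the poly-A controls. Tgfb1, a ligand, differed by 2.04 (SE 0.23, limma adjusted p = 3.89e-04), at 7.75 ± 0.24 against 5.70 ± 0.40 (SD, n = 3). The ligands Tgfb2 and Tgfb3, given in addition to the genes of the rule, differed by 3.80 and 5.17. Grem1, a BMP antagonist, differed by 8.91 and Id3, a target of BMP signalling, by 5.90, whereas Fst, follistatin, which binds activins, differed by -2.62. The related genes Id1 and Id2, also given in addition, did not follow Id3. Id1 differed by 0.50 (limma adjusted p = 0.528) and Id2 by -1.14 (limma adjusted p = 0.00515). Tgfbr1, a receptor of TGF-beta, stood at 9.95 ± 0.18 in TDESM and 9.77 ± 0.31 in TDECC and did not pass the threshold; it was picked after its values were seen. Camera gave adjusted p = 0.0101, and adjusted p = 0.206 with an estimated correlation. The counts adjusted over the list alone were the same.

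Among 27 genes of the PDGF, HGF, FGF and IGF families, 13 were higher and 1 lower, with a median of -0.82 centred on the poly-A controls. Igfbp7 was higher by 8.59 and Vegfc, a lymphatic growth factor, by 5.51, and camera gave adjusted p = 0.00162 (adjusted p = 0.206 with an estimated correlation). Met, the HGF receptor, differed by -0.62 (limma adjusted p = 0.0493) with both strains near background. Its call was lost without TDECC replicate 1 or 3 (adjusted p = 0.0740 and 0.0810) or any 1 TDESM replicate (adjusted p up to 0.160). It was also lost with the replicate block or centred on housekeeping or ribosomal protein genes. Hgf itself, picked after its values were seen, stood at 3.86 in TDESM and 4.08 in TDECC. Of 13 EGF family genes, 1 was higher and 5 lower (8 lower adjusted over the list alone; camera adjusted p = 0.0565). Ereg, epiregulin, differed by -4.48, Erbb2 by -1.87 and Nrg1, neuregulin, by 2.51, or 1.35 with the mean of its probe sets. The list passed without TDECC replicate 1 (adjusted p = 0.0468) or 3 (adjusted p = 0.0317), with the replicate block and centred on housekeeping genes. Tgfa, a ligand of Egfr read by a shared probe set, stood at 9.55 ± 0.09 in TDESM and 10.46 ± 0.74 in TDECC (limma adjusted p = 0.0715). On TDECC replicate 3 it read 9.61, within the TDESM values of 9.45 to 9.61. Tgfa passed without that array (-1.34, adjusted p = 4.42e-04), with the mean of its probe sets or with the replicate block. Egfr differed by -0.56 (limma adjusted p = 0.0409) by 1 of its 3 probe sets. Its call was lost without TDECC replicate 1 or 2 (adjusted p = 0.0830 and 0.0926) or any 1 TDESM replicate (adjusted p up to 0.134). It was also lost with the mean of its probe sets (-0.32) or centred on housekeeping genes.

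Among 23 metalloproteinases and their inhibitors, 14 were higher and 1 lower in TDESM, with a median of 0.07 centred on the poly-A controls. Adamts1 was higher by 7.02 and Mmp16 by 5.08, while Mmp15 differed by -3.40 (camera adjusted p = 4.57e-04; adjusted p = 0.175 with an estimated correlation). Of 29 Wnt pathway genes, 10 were higher and 3 lower, with a median of -1.04 centred on the poly-A controls. Ccn4 differed by 5.73 and the receptor Fzd1 by 3.73, whereas the ligand Wnt4 differed by -3.50. The Wnt list's camera adjusted p was 0.0489, and adjusted p = 0.199 with an estimated correlation. It was 0.0522 without TDECC replicate 1, 0.0606 without TDESM replicate 1, 0.0547 centred on housekeeping genes and 0.0530 without the dimmest genes, so this call was not stable.

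Of 18 sterol and fatty acid synthesis genes, 16 were lower in TDESM and 1 higher. Idi1, which makes isoprenoid precursors, differed by -2.37 and Fdft1, squalene synthase, by -2.13, each with little spread between arrays. Scd, a fatty acid desaturase near background in both strains, differed by 0.71, or by -0.56 centred on the poly-A controls. Camera gave adjusted p = 3.28e-06, and adjusted p = 0.206 with an estimated correlation.

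The other lists did not pass by camera. Among 27 chemokine and cytokine genes 6 were higher and 9 lower (adjusted p = 0.211; the same counts adjusted over the list alone), with Cxcl12 at a difference of 7.46, and Cxcl6 at -7.90 and Il1a at -7.43; the list passed centred on the poly-A controls (1.28e-05) and without the dimmest genes (0.00142). Of 21 glycolysis and hypoxia genes, 0 were higher and 7 lower (5 adjusted over the list alone), including Ndrg1 (-6.16) and Egln3 (-5.75), with adjusted p = 0.0550. That list passed without TDECC replicate 1 (adjusted p = 0.0442) or 3 (0.00627) or TDESM replicate 3 (0.0331), and also with cyclic loess, the replicate block, trend and robust eBayes, and centring on housekeeping genes or the poly-A controls. Of 33 cell cycle genes, 9 were higher and 2 lower (adjusted p = 0.215, but 0.0313 without TDECC replicate 1; median 0.38, from 0.10 to 0.58 leaving out each array in turn, or -0.89 centred on the poly-A controls). Kif20a differed by 1.86 and Birc5 by 1.62, calls lost when centred on the poly-A controls, and Ccnd1, cyclin D1, by -2.92. Mki67, picked after its values were seen, stood at 10.11 ± 0.29 in TDESM and 10.05 ± 0.57 in TDECC. Of 24 interferon genes 4 were higher and 8 lower (adjusted p = 0.295), among them Ifit2 (3.96), Isg15 (1.76, not past the threshold centred on the poly-A controls) and Psmb8, an immunoproteasome subunit (-4.37). Of 20 glutathione and xenobiotic genes, 6 were higher and 7 lower (7 and 8 adjusted over the list alone; adjusted p = 0.860), among them Cyp1b1 (7.82), Gsta1 (3.86) and Aldh3a1 (-4.18). That list's median was -0.40, its mean 0.26 and camera's direction down.

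Of 12 hedgehog genes 3 were higher and 2 lower (adjusted p = 0.703; median -0.09, or -1.36 centred on the poly-A controls, mean 0.37 and camera direction up). Boc differed by 3.42, Gli2 by 2.04 and Disp1 by -0.90. The Disp1 call was lost without TDECC replicate 3 (adjusted p = 0.0621), without any 1 TDESM replicate (adjusted p up to 0.0888) or centred on housekeeping genes. Gli1, a target of the pathway picked after its values were seen, stood at 5.30 in TDESM and 5.53 in TDECC. Of 16 Notch genes 5 were higher and 4 lower (6 and 5 adjusted over the list alone; adjusted p = 0.754), with Hey2 at 5.72, Hey1 at 3.21 and Jag2 at -2.39. Of 21 ribosomal protein genes 0 were higher and 1 lower, Rpl5 (-0.48), whose call was lost without TDESM replicate 2 (adjusted p = 0.0729) or 3 (0.0709), with the replicate block, centred on housekeeping genes and adjusted over the list alone; the list's adjusted p was 0.703.

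Markers of other cells mostly stood at low levels. Of 22 leukocyte genes 0 were higher and 0 lower by limma (adjusted p = 0.959 by camera, direction up, with a median of 0.05, or -0.0042 without TDESM replicate 2, and a mean of -0.04), and Ptprc, CD45, picked after its values were seen, stood at 3.80 in TDESM and 3.68 in TDECC. Over 76 genes of 4 other lineages, the median level was 4.48 in TDECC and 4.49 in TDESM. This median served as the background level, so it cannot show that these markers are absent. Probe sets of a control transcript that was not added read lower, at 2.80 to 3.53 in TDECC and 2.87 to 3.23 in TDESM. Of 16 endothelial genes 3 were higher and 1 lower (3 and 0 adjusted over the list alone, with adjusted p = 0.529 by camera). Flt1 differed by 1.84 (1.18 with the mean of its probe sets) and Egfl7 by 1.45, calls lost centred on the poly-A controls. Pecam1 differed by -0.37, a call lost with the replicate block or centred on housekeeping genes. It was also lost without TDECC replicate 2 or 3 (adjusted p = 0.0900 and 0.0848) or any 1 TDESM replicate (adjusted p up to 0.132). Pecam1 read 3.43 on each TDESM array, so leaving 1 of them out kept the difference at -0.37 and changed only its precision. Of 21 hepatocyte genes 3 were higher and 2 lower (3 and 1 adjusted over the list alone; adjusted p = 0.754), with Arg1 at 3.34, Apoc3 at 1.36 (lost centred on the poly-A controls) and Ass1 at -5.44. Alb, albumin, picked after its values were seen, stood at 4.46 in TDESM and 4.16 in TDECC by a shared probe set, and passed with the mean of its probe sets (adjusted p = 0.0175). Of 17 skeletal and cardiac muscle genes 4 were higher and 1 lower (adjusted p = 0.703). Tnnt2 differed by 2.0 (0.90 with the mean of its probe sets), Tnnc1 by 1.71 (adjusted p = 0.0533 without TDESM replicate 3, and lost centred on the poly-A controls) and Myh1 by -1.21 (-0.79 with that mean), the last by a shared probe set while another of its probe sets passed in the other direction. Of 13 portal fibroblast and mesothelial genes 6 were higher and 2 lower, including Lox, Thy1 and Entpd2 (-4.03), with a median of 0.18, or 3.30 without the dimmest genes, 0.36 with the mean of probe sets and -1.09 centred on the poly-A controls. That list's adjusted p was 0.0550, or 0.0466 without TDECC replicate 3 and 0.0485 without TDESM replicate 1, and it passed without the dimmest genes, with the mean of probe sets, with trend and robust eBayes and centred on the poly-A controls. With an estimated correlation 0 of the 26 lists passed by camera, 7 had an unadjusted p under 0.05, and fry called 20.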

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

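All tests in this part were chosen after the results were seen. The poly-A control transcripts, which are added to the RNA before labelling and enter no comparison above, were brighter on the TDESM arrays by 1.27 on the log2 scale, at 8.36 ± 0.33 against 7.08 ± 0.12 in TDECC (SD, n = 3). This signal in data outside the comparison is why it is listed here. Of 24 such probe sets 20 were higher past the threshold by limma and 0 lower.

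Scaling arrays to equal distributions takes out an evenly brighter hybridisation or scanning of the TDESM arrays. The hybridisation controls, which differed by 0.092, are therefore no evidence on it by themselves. An even brightening would, scaled or not, move both kinds of control alike. Only the poly-A controls rose, by 1.27, which argues against it. Loss of 5-prime sequence in TDECC labelling is argued against by the 3-prime poly-A probe sets, which differed by 1.34. All 4 poly-A transcripts rose by a like amount, the smallest by 1.09, so another ratio of control RNA to sample mRNA stays open. It may come from the amount added or from a lower mRNA content of TDESM, and these cannot be told apart since both go with the strain. Centred on these controls, 11282 genes would be lower and 905 higher in TDESM.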

How the results depend on the processing

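The poly-A centring and the test of other splits were chosen after seeing the data. For the 101 named genes other than Acta2, 1322 values over the alternatives kept their direction and side of the threshold, 53 lost and 9 gained it, and 12 changed sign; for the lists these counts, by the test's direction and threshold, were 347, 17, 21 and 0 by camera and 18, 0, 7 and 1 by fry. List medians changed sign 20 times, 11 of them centred on the poly-A controls, where the shift of all genes shows the cause, and were near 0 for the others. Acta2 stayed past the threshold under every alternative run on it, with differences from 3.72 to 5.54. The count of genes was 6264 with cyclic loess, 5938 centred on ribosomal protein genes, 6068 with the mean of all probe sets, 6057 with trend and robust eBayes and 5269 without the dimmest genes. Centred on housekeeping genes it was 5476, 57.7% of them higher, with the median gene at 0.11. Leaving out each array in turn gave 4605 to 6437 genes, 2474 to 3425 higher and 2131 to 3035 lower. The replicate block gave 5342 genes; the numbers did not pair the arrays, with deviations correlated at -0.07, 0.02 and -0.14. Centred on the poly-A controls, 12187 genes passed, 905 (7.43%) higher and 11282 lower. Of the calls on deposited values 51.7% were higher, and 378 of those calls passed with the other sign once centred. The alternative's construction, a shift of all genes by -1.27, shows the cause of the split by direction. Limma's adjusted p there followed size alone: 0.0877 for Kif20a (0.59) and 0.103 for Scd (-0.56). On deposited values their TDECC SDs were 0.90 and 0.16. The 12187 calls are thus in effect a cut on the size of the difference. The same centring turned Cd44 (-0.12), Scd (-0.56), Fap (-1.17), S100a4 (-0.84), Tgfbr1 (-1.10), Mki67 (-1.22), Ptprc (-1.16) and Alb (-0.98). Leaving out each array in turn, Fap ranged from -0.047 to 0.23 (turned without TDECC replicate 2), Mki67 from -0.21 to 0.35 (turned without TDECC replicate 2 or TDESM replicate 1) and Dcn from -0.35 to 0.017 (turned without TDESM replicate 3); the cause was not tested. Requiring a log2 difference of 1 left 3623 genes, 1906 higher and 1717 lower, by construction. Testing 31042 probe sets in place of genes gave 11470, 5559 higher and 5911 lower, by construction of a larger number of tests. An estimated correlation left 0 of 26 lists past the threshold by camera, with 7 at an unadjusted p under 0.05, where the preset gave 12 and fry 20. Fry asks another question. For camera, the estimated correlation of the contractile (-0.037), fibroblast marker (-0.023), Wnt (-0.017) and stellate cell (0.0043) lists was below the preset of 0.01. A higher correlation therefore does not explain why these lists lost their calls. With an estimated correlation camera uses the residual degrees of freedom of the 6 arrays, with a preset one those of all genes. At a like correlation the estimated form thus gives every list a larger p. The unadjusted camera p of the contractile list went from 4.48e-08 to 0.00395. The estimate was above the preset for the others of the 12, where the share of each cause was not tested. Fry's direction for the glutathione and xenobiotic list (median -0.40, adjusted p = 0.0146) was up where camera's was down, and its mean was positive. The values had no detection calls, so differences against a strain at background, near 4.48, are likely compressed, and the 54% recovery of a log2 change of 1 in simulated data limits small ones. Only 10 splits of the 6 arrays into 3 and 3 exist, too few for a share under 0.05: the strains gave 6065 genes, in 1 split, and the highest other split gave 0. Every other split mixes both strains within each group, so the strain difference widens the spread there. The 0 is therefore no measure of false calls.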

Other observations

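After the data were seen, 22 pairs were looked up. They paired a ligand with a receptor, except for Grem1, a BMP antagonist, which was paired with the ligand Bmp4. Both genes passed the threshold in 4 pairs, in opposite directions in 3. Since 42.7% of all genes passed, unrelated genes often pass together, and these counts show no link between the paired genes. The pairs below are a selection. Il33, an alarmin cytokine, stood at 13.93 ± 0.28 in TDECC and 8.0 ± 0.23 in TDESM, while its receptor Il1rl1 stood at 4.03 ± 0.56 and 12.51 ± 0.13 (SD, n = 3; limma adjusted p = 8.42e-07 for each), or 4.59 and 10.10 with the mean of its probe sets. Wnt4 was at 10.63 in TDECC and 7.12 in TDESM, and the receptor Fzd1 at 6.45 and 10.18. Pdgfa was at 11.43 and 10.87, without passing the threshold, and Pdgfra at 4.66 and 9.64. Cxcl12 was at 4.44 in TDECC and 11.90 in TDESM, while its receptor Cxcr4 was near background in both, at 4.35 and 4.33, and its other receptor Ackr3 was at 7.48 and 6.81, not past the threshold. Il11ra1, a receptor of interleukin 11, was at 4.35 in TDECC and 7.94 in TDESM, while Il11 itself did not pass the threshold (5.79 and 5.81). These are RNA levels of each strain, and no signalling was measured.

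Within TDECC the arrays differed from each other on several genes. Car1, a carbonic anhydrase, stood at 3.53, 13.68 and 12.25 on TDECC replicates 1, 2 and 3. Cdh17 stood at 6.28, 12.63 and 6.49, Tff2 at 4.64, 10.20 and 6.05, and Muc13 at 4.62, 9.80 and 5.63, and Nr4a1 at 5.62, 5.57 and 10.60. These genes were picked because they varied.

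The tests in the next paragraphs were all chosen after the results were seen. TDECC arrays differed more from each other than TDESM arrays did, with a median SD over genes of 0.244 against 0.12. A single outlying array is argued against by the smallest median difference between TDECC arrays, 0.26, which exceeded the largest between TDESM arrays, 0.17, and noise of dim probe sets by a ratio of SDs of 2.65 in the brightest genes. The cell cycle list spread more over TDECC arrays than all 10000 random lists (percentile 100), yet 7 of the 26 lists lay above the 99th percentile. Random lists were drawn gene by gene, so a list whose members vary together (estimated correlation 0.72 for cell cycle) spreads more than they do. A difference in proliferation may be part of it but is not singled out. As the whole cause it is argued against, since with the cell cycle direction taken out the deviations were still 2.23 times those of TDESM. Labelling of TDECC replicate 3, whose 5-prime minus 3-prime signal stood apart on 3 of 6 control transcripts (thr at -1.38 against -3.46 on replicate 1), stays open as part of it, as does a difference between cultures, since the labels do not say how replicates were made; as the whole cause labelling is argued against by the 0.28 between TDECC replicates 1 and 2.

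Klhl9 and Mtap, a methylthioadenosine phosphorylase, were at background in TDECC, at 3.16 and 3.08, and at 10.14 and 11.94 in TDESM, though the mean of the 3 Mtap probe sets was 3.53 in TDECC and 8.59 in TDESM, with 1 of them at only 5.67 in TDESM. In the gene order of assembly GRCr8 they lie in a run of 8 genes (Hacd4 to Elavl2) below a level of 5.6 in TDECC, 7 of them at most 5. The run lies between Focad (8.02) and Caap1 (9.12, or 6.94 with the mean of its probe sets). Probe sets that read nothing stay open for the 4 genes that were not above a log2 level of 6 in TDESM either, Cdkn2a (3.34) and Cdkn2b among them; the others were the basis on which the run was found, and Elavl2 among them was at 5.87 with the mean of its probe sets. Chance order stays open: 4.86% of random gene orders held such a run, but this was under 5% in 3 of 18 choices of the levels, which were set after the values were seen, and ranged from 2.75% to 100%. Loss of the segment in TDECC is a candidate explanation that cannot be told apart from silencing, with a highest TDECC level of 5.54 inside the run, that of Cdkn2b, which was 5.58 in TDESM.

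The same search gave runs as strong or stronger elsewhere, in both strains, so such a run does not by itself point to loss. In TDECC a run of 12 genes from Gprasp2 to Tceal1 held 5 genes on in TDESM, a count reached in 0.28% of random gene orders, and a run of 7 from Rab9b to Pwwp3b, separated from it by Morf4l2 alone, held 4 (4.86%, as for the run with Mtap). At background in TDESM were runs of 11 genes from Sh3bgr to Ripk4, with 5 on in TDECC (0.02%), of 8 from C4bpa to Il10 and of 5 from Fggy to Cyp2j3, each of the last with 4 on.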
